A study of Rattus norvegicus with 2 samples.

How the data were processed

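Heart RNA of 3 groups of rats was compared on 2 two-colour arrays, high-salt vehicle against normal diet and benidipine against high-salt vehicle. Total RNA was isolated with Trizol, amplified and labelled with Cy3 or Cy5 using an Agilent low-input linear amplification kit, per the labels' protocols. The dyes were taken from the labels, which place the treated sample of each comparison in Cy3 (channel 2) on both arrays, so every ratio is Cy3 over Cy5. The scanner, the extraction software and the filter that left 51 probes on the first array only and 63 on the second only are not given in the sources used here.

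The authors deposited, for each array, a linear intensity per probe and channel. The lowest intensities were 199 in Cy5 and 132 in Cy3 on the first array and 192 and 141 on the second, and the deposited background column was 0 for all but 2 probes per array, so the intensities hold no sign of background subtraction. Before normalization 98.8% of probes on the first array and 96.9% on the second were dimmer in Cy3 than in Cy5, so the deposited intensities were not dye-normalized. Every listed probe had a distinct Agilent name, and no control spots were listed. The files give no flags for outliers or for signal above background.

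The authors' deposited value table of the series holds log2 ratios by feature number. Its scale and direction were not stated and were found from the values. Over 9 quantiles its columns differed by at most 0.025 and 0.013 from loess-normalized log2 Cy3 over Cy5 without background correction, and by up to 0.75 and 0.41 from Cy5 over Cy3. Its medians were -0.019 and -0.012. Its 229 and 172 empty cells equal the probes missing from an array plus those saturated in Cy5. The table was used as an alternative for counts, medians, correlations and sums over its features, and for no named probe, because its feature numbers are not paired with probe names in the tables used here.

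Background was corrected with normexp (offset 50) and each array was normalized by loess in limma 3.58.1 under R 4.3.3. All listed probes were kept, saturated ones included. With 1 array per comparison there is no residual variance among samples, so changes are described by size, at 2-fold for each array and 1.5-fold for changes on both, as fixed before the data were examined. The number of arrays limits the precision, and no interval across animals can be given. For values compared between arrays, channel values were taken after loess and Aquantile normalization, a step chosen after seeing the data.

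Chance overlap was computed from the lengths of the lists, overall and within 20 bins of mean intensity, and from 100 simulated pairs of arrays that share the vehicle sample with no effect, at 3 shares of variance from the RNA samples. The ratio step was tested on simulated data built from each array's own intensities with 200 changed probes. For the first comparison, run on 20437 probes, 100% of 4-fold changes among probes brighter than the median and 78.6% among dimmer ones were returned at 2-fold or more, and 45.5% and 32.1% of 2-fold changes. For the second, run on 20449 probes, the figures were 100% and 87.5% for 4-fold changes and 42.1% and 25.6% for 2-fold changes. Median fitted log2 ratios of dimmer probes with a 4-fold change were 1.56 and 1.43, so planted changes of dim probes were understated. This does not cover dim probes picked from the data for a large ratio. Of unchanged probes, 19 of 10116 brighter and 36 of 10121 dimmer ones reached 2-fold in the first simulation. In the second, 20 of 10115 and 47 of 10134 did.

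The rule for named items, fixed before the data were examined, was the 12 highest and 12 lowest ratios per array among genes with a symbol, the strongest opposite and same-direction genes, changed members of fixed gene lists, and a short set of heart genes. Because no probe could be paired with a gene, the 2 highest and 2 lowest probes per array are named instead, and the 33 gene lists were not evaluated, with 0 members matched. Alternatives covered the authors' values, median centring, no background correction, filters on dim probes and other size thresholds, and, added after seeing the data, saturated probes left out, same-dye values between arrays, probes brighter than the median, and no background correction together with saturated probes left out. Figures were drawn with matplotlib 3.10.9.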

Results

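Hearts of rats aged 21 weeks were profiled on 2 two-colour Agilent oligonucleotide arrays, on which RNA of a pair of samples labelled with different dyes competes for the same probes. The 3 RNA samples came from rats on a normal diet, rats on a high-salt diet given vehicle, and rats on a high-salt diet given benidipine, a dihydropyridine blocker of voltage-gated calcium channels used against high blood pressure. On the first array the high-salt vehicle sample carried Cy3 and the normal-diet sample Cy5. On the second array the benidipine sample carried Cy3 and the high-salt vehicle sample Cy5. Each comparison had 1 array, with no replicate and no dye swap, so no error between animals can be given, no p-value was computed, and each ratio describes these samples only. The rat strain, the number of animals behind each RNA sample, the salt content and the drug dose are not given in the sources used here.

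The first array listed 20437 probes and the second 20449, of which 20386 were on both. Median intensities were 1373 in Cy5 and 536 in Cy3 on the first array, and 838 in Cy5 and 460 in Cy3 on the second. The scanner ceiling of 65535 was reached by 166 Cy5 and 34 Cy3 values on the first array and by 121 Cy5 and 34 Cy3 values on the second. Probes are named by their Agilent identifiers, because the tables used here pair these with no gene name, and so no gene, pathway or cell type marker is named. No genomic position is given for the same reason.

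The first array addressed what a high-salt diet changed in the heart. At least 2-fold higher signal in high-salt vehicle than in normal-diet heart was found for 446 probes, and at least 2-fold lower signal for 181, together 3.07% of the 20437 probes. At 3-fold the counts were 87 higher and 15 lower. Higher ratios made up 71.1% of the 2-fold changes, but higher always means brighter in Cy3, without a dye swap. Comparing the Cy5 values of the arrays gave 633 higher and 611 lower probes, 50.9% higher. Of the 445 shared higher probes 115 were among the 633, and of the 180 shared lower probes 31 were among the 611. Differences between spots and arrays enter these values, so their split does not decide the direction of the within-array changes. In 59 of the 446 higher probes the normal-diet channel was saturated, which overstates the ratio, and in 34 of these both channels were saturated, which leaves no valid ratio. Without saturated probes, 387 were higher and 181 lower. In the authors' deposited normalized values, which carry no background correction, 147 probes were at least 2-fold higher and 28 at least 2-fold lower, a split of 84.0% higher.

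The highest ratio on the first array belonged to A_42_P815318. Its signal was 24.8-fold higher in high-salt vehicle than in normal-diet heart, from intensities of 39518 in Cy3 and 5408 in Cy5. The second highest was A_43_P13140, at 9.66-fold, from intensities of 2224 and 957. The vehicle RNA gave only 375 for A_43_P13140 when it was measured again in Cy5 on the second array, and the Cy5 values alone put vehicle below normal diet, with a log2 difference of -0.86. The lowest ratio belonged to A_42_P552092, 7.50-fold lower in high-salt vehicle, from intensities of 616 in Cy3 and 12246 in Cy5. A_43_P12619 was 5.15-fold lower, from dim intensities of 221 and 840, and its ratio was 2.31-fold without background correction. The 12 highest log2 ratios spanned 2.57 to 4.63 and the 12 lowest -2.91 to -1.63.

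The second array addressed what benidipine changed in the heart under a high-salt diet. At least 2-fold higher signal in the benidipine than in the high-salt vehicle sample was found for 403 probes, and at least 2-fold lower signal for 234, together 3.12% of 20449 probes. At 3-fold, 39 probes were higher and 14 lower. The vehicle channel was saturated in 47 of the 403 higher probes, 34 of them with both channels saturated, and in 2 of the 234 lower probes. Without saturated probes, 356 were higher and 232 lower. In the authors' deposited values 119 probes were at least 2-fold higher and 19 at least 2-fold lower, so that 86.2% of these changes were higher, against 63.3% in the background-corrected values with saturated probes kept. Leaving out background correction alone gave 89.5% higher, and leaving out saturated probes alone 60.5%. Comparing the Cy3 values of the arrays gave 851 higher and 937 lower probes, 47.6% higher, but these values too hold differences between spots and arrays.

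The highest ratio on the second array belonged to A_43_P13418, 5.05-fold higher with benidipine than with vehicle, from intensities of 1115 and 654. A_42_P500847 followed at 4.76-fold, from intensities of 11470 and 6719. Both of these probes were lower in high-salt vehicle than in normal-diet heart on the first array, A_43_P13418 by 4.15-fold and A_42_P500847 by 5.07-fold. The lowest ratio belonged to A_42_P815318, the probe with the highest ratio on the first array. Its fitted ratio was 8.27-fold lower with benidipine than with vehicle, and 7.90-fold lower without background correction. The vehicle channel was saturated at 65535 while the benidipine channel read 3106, so both values understate the difference. A_43_P11602 was 4.56-fold lower with benidipine and had been 6.29-fold higher with high salt. The 12 highest log2 ratios spanned 1.82 to 2.34 and the 12 lowest -3.05 to -1.65. Of these 12 highest probes 5 had a ratio of the opposite sign on the first array, 3 of them at 1.5-fold or more, and of the 12 lowest 9 did, 5 of them at 1.5-fold or more.

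**Figure D1:**
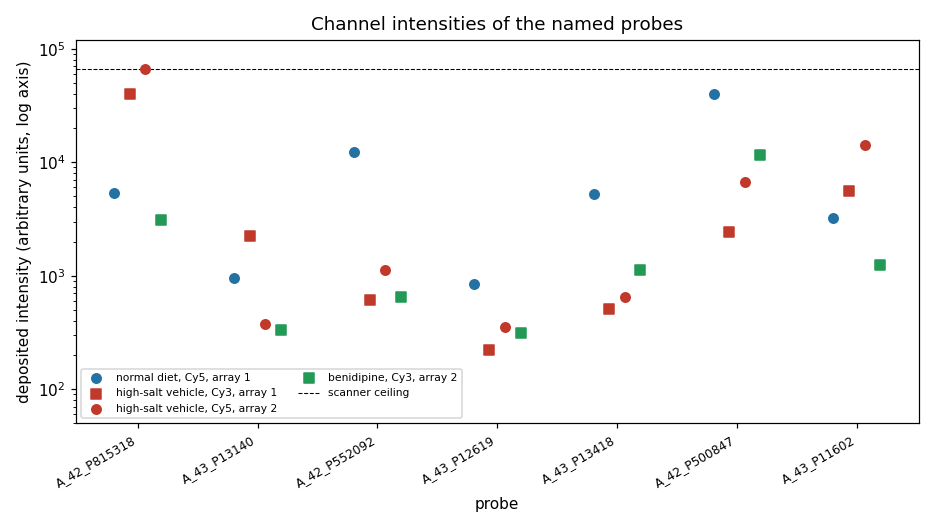
Deposited intensities (log axis, arbitrary units) of the 7 probes with the highest or lowest ratios, with circles for Cy5, squares for Cy3 and colours for the RNA sample. The vehicle RNA was measured once on each array, and for A_43_P13140 it read 2224 in Cy3 on the first and 375 in Cy5 on the second, beside 957 for normal diet in Cy5 on the first.

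The arrays were then set side by side to ask whether probes changed with high salt moved back with benidipine. In the authors' deposited values, 123 of 20215 probes with a value on both arrays were at least 1.5-fold changed on each array in opposite directions, and 10 in the same direction. Of the opposite probes, 74 were higher with high salt and lower with benidipine, and 49 were lower with high salt and higher with benidipine. Independent lists of these lengths would share 11.1 probes in opposite and 13.8 in the same direction. Among the 28 probes at least 2-fold lower with high salt, 27 had a ratio of the opposite sign with benidipine, 21 of them at least 1.5-fold higher, and the median log2 ratio with benidipine was 0.80. Among the 145 probes at least 2-fold higher with high salt that had both values, 98 had the opposite sign, 42 were at least 1.5-fold lower and 1 at least 1.5-fold higher with benidipine, and the median log2 ratio was -0.18.

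With background correction and all probes kept, the counts at 1.5-fold were 340 opposite and 358 same-direction probes, against 240 and 255 for independent lists drawn within bins of like intensity. Of the 358 same-direction probes, 67 were saturated in Cy5 on at least 1 array. Opposite probes outnumbered same-direction probes in these values once saturated probes were left out, with 337 against 291, or the dimmest 25% of probes, with 189 against 99, and among probes brighter than the median, with 149 against 75. Of the 445 shared probes at least 2-fold higher with high salt, 85 were at least 1.5-fold lower with benidipine and 108 at least 1.5-fold higher, and of the 180 at least 2-fold lower, 36 were at least 1.5-fold higher and 34 at least 1.5-fold lower. With all probes kept, at 2-fold on both arrays, 43 probes went opposite ways and 75 the same way. On each array 34 of the at least 2-fold higher probes were saturated in both channels and hold no valid ratio. Neither the 108 nor the 75 was counted without saturated probes. Of the 87 probes at least 3-fold higher with high salt, 29 were at least 1.5-fold lower with benidipine and 10 at least 1.5-fold higher. Of the 15 probes at least 3-fold lower with high salt, 9 were at least 1.5-fold higher with benidipine and 0 at least 1.5-fold lower.

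Across all probes, which are not independent replicates, the log2 ratios of the arrays were nearly unrelated, with Pearson's r of 0.03 and Spearman's rho of 0.04 with background correction and -0.09 and 0.02 in the authors' values. The same vehicle RNA is the numerator on the first array and the denominator on the second, so any chance deviation of that sample gives opposite ratios without an effect of the drug. In simulated arrays with no effect, built on values without background correction and without saturated probes, the number of opposite probes averaged 12.4 when no variance came from the RNA samples, 101 when a share of 0.5 did, and 242 when all of it did. The observed number on those values was 125, with 10 in the same direction. Simulated same-direction numbers there averaged 18.1, 8.56 and 2.17. At a share of 0.5 the highest simulated numbers were 140 opposite and 16 same-direction probes, so the observed numbers lie within that range. The covariance was -0.0070, against simulated values of 0.000052, -0.0194 and -0.0388 for these shares. The share of 0.5 thus gave the observed counts but a more negative covariance than observed. Simulated ratios were drawn from the observed ones, any real changes included, so a match in counts cannot exclude an effect of the drug. With background correction the corresponding simulated numbers were 238, 563 and 959, against 340 observed. The simulated same-direction numbers were 248, 126 and 36.3, with a highest of 287, and the 358 observed exceeded all of them.

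**Figure D2:**
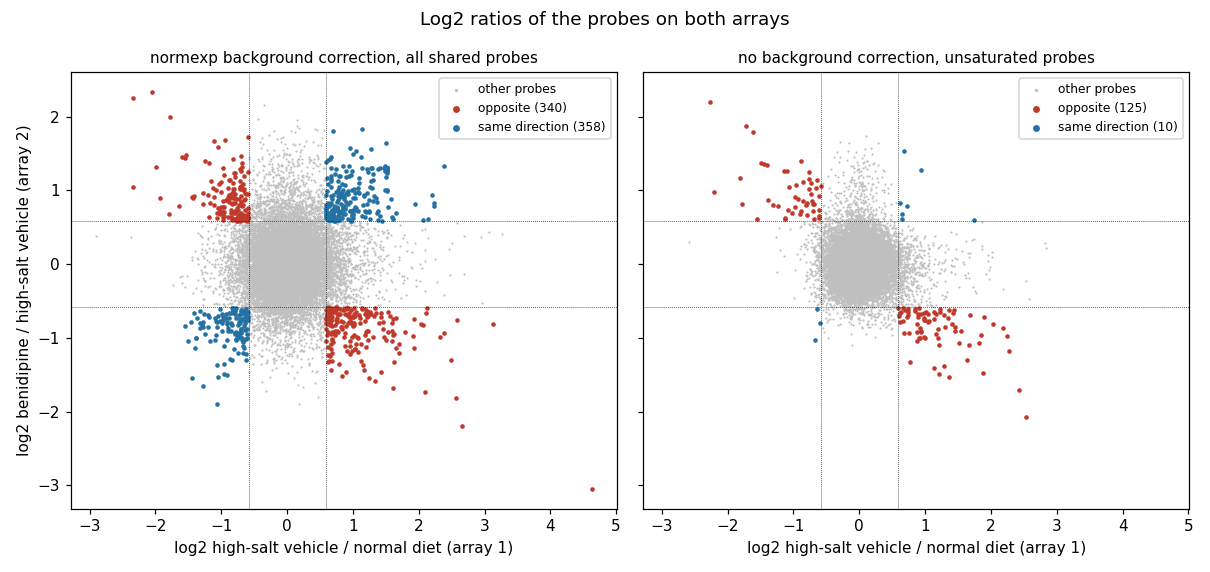
Log2 ratio of high-salt vehicle over normal diet (horizontal) against log2 ratio of benidipine over high-salt vehicle (vertical), a point per probe, with dotted lines at 1.5-fold. The left panel holds all 20386 shared probes after background correction, with 340 opposite and 358 same-direction probes, and the right panel holds the 20215 unsaturated probes without it, with 125 and 10.

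No array set the benidipine sample against the normal-diet sample, and the sum of both log2 ratios gives that comparison indirectly. By this sum 1068 of 20386 probes were at least 2-fold higher and 665 at least 2-fold lower in benidipine than in normal-diet heart, and in the authors' values 244 and 60. For A_42_P500847 the sum was -0.09, for A_43_P13418 0.28 and for A_43_P11602 0.46. For A_42_P815318 it was 1.59, a value that the saturated vehicle channel on the second array overstates, and for A_42_P552092 it was -2.52. For A_43_P13140 it was 3.68 and for A_43_P12619 -1.995. Both of these sums rest on vehicle readings that differed between the arrays. For A_43_P12619 the normalized vehicle value was lower in Cy3 on the first array than in Cy5 on the second. For A_43_P13140 it was higher in Cy3, by 4.13 on the log2 scale. That gap is larger than the 3.68, so the sum cannot show a difference from normal diet for A_43_P13140. In the authors' values, 18 of the 28 probes at least 2-fold lower with high salt were within 1.5-fold of normal diet by this sum, and 32 of the 145 at least 2-fold higher. In the background-corrected values these numbers were 36 of 180 and 60 of 445. A dye bias of a probe enters this sum with the same sign from each array.

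The vehicle RNA was measured in Cy3 on the first array and in Cy5 on the second, which gave a comparison of a sample with itself across dyes and arrays. This comparison put 1504 of 20386 probes at least 2-fold apart, 7.38%, with a robust SD of 0.45 on the log2 scale. Comparisons of different samples in the same dye between the arrays were of like spread, with 1244 probes at least 2-fold apart for vehicle over normal in Cy5 and 1788 for benidipine over vehicle in Cy3. Ratios within an array cancel spot differences and had a robust SD of 0.33 on each array. Of the 445 shared probes at least 2-fold higher on the first array, 176 were at least 1.5-fold higher by the Cy5 values and 130 had the opposite sign. Of the 180 lower probes, 59 were at least 1.5-fold lower and 54 had the opposite sign. For 225 of the 445, vehicle was at least 2-fold brighter in Cy3 than in Cy5. Picking probes on a high first-array ratio favours high vehicle readings in Cy3, which raises the 225. Saturated probes were kept, and 59 higher probes on the first array were saturated in Cy5, 34 of them in both channels. The ceiling limits their Cy5 differences and can overstate vehicle Cy3 over Cy5. These counts, and those below for the second array, were not repeated without saturated probes. On the second array 262 of 402 higher and 156 of 234 lower probes reached 1.5-fold by the Cy3 values, while 76 and 22 had the opposite sign. For A_42_P500847 the same-dye log2 differences were -2.15 and 2.44. For A_42_P815318 the Cy3 difference of benidipine from vehicle was -3.65, and its Cy5 difference is not given because vehicle was saturated there.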

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

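The counts in this part are given in a fixed order, which is higher and lower on the first array, higher and lower on the second, opposite and same-direction probes on both, and higher and lower for the indirect comparison of benidipine with normal diet. With background correction and loess they were 446, 181, 403, 234, 340, 358, 1068 and 665, and Pearson's r was 0.03. The authors' values gave 147, 28, 119, 19, 123, 10, 244 and 60, and r turned to -0.087. Without background correction they were 217, 27, 179, 21, 128, 80, 358 and 59, and r turned to -0.017. With saturated probes left out as well, an alternative chosen after seeing the data, they were 151, 27, 127, 19, 125, 10, 260 and 59, and r turned to -0.090. Median centring in place of loess gave 1929, 87, 1812, 125, 233, 2494, 4474 and 1070 with r of 0.53, a setting that leaves the trend of the dyes with intensity in the ratios. With the dimmest 25% of probes on each array left out they were 299, 44, 254, 58, 189, 99, 382 and 132, and r turned to -0.062. Among probes brighter than the median, chosen after seeing the data, they were 216, 33, 225, 33, 149, 75, 203 and 41, and r turned to -0.11. Same-dye values between arrays, also chosen after seeing the data, gave 633, 611, 851, 937, 257, 1916, 2252 and 2510 with r of 0.53, and in these values any difference in brightness between the spots of a probe enters both comparisons with the same sign. At 1.5-fold the counts on single arrays were 1538, 1063, 1476 and 1222, with 2782 and 2419 for the indirect comparison, and at 3-fold they were 87, 15, 39 and 14, with 313 and 118. At 2-fold on both arrays, with saturated probes kept, there were 43 opposite and 75 same-direction probes. Leaving out saturated probes alone kept every count within 1.5 times (387, 181, 356, 232, 337, 291, 979 and 664) and brought r to 0.00026. The share of higher ratios ran over these settings from 50.9% to 95.7% on the first array and from 47.6% to 93.5% on the second, with the lowest share in the same-dye values. The causes of these shifts were not tested beyond what each setting removes. Where no filter applied, the setting is the reported one, and settings that need a p-value of the scanner software, several probes of a gene, or gene lists could not be run. No paired analysis was possible because each comparison had 1 array, and no replicate could be left out. Most of the lower probes were dim, since 44 of 181 on the first array and 58 of 234 on the second were left without the dimmest 25% of probes.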

Other observations

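The test of a deviating vehicle sample in the first pattern was chosen after the result was seen, as were the values without saturated probes and the same-dye values. The other tests were written before their results were seen.

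In the background-corrected values, probes at least 3-fold changed by high salt went the opposite way with benidipine more often than the same way, 38 against 10 among those at least 1.5-fold changed on the second array. With all probes kept this did not hold at lower limits, since among probes at least 2-fold changed by high salt 121 went the opposite way and 142 the same way, while at 1.5-fold on both arrays opposite probes were more numerous without saturated probes (337 against 291), without the dimmest 25% (189 against 99) and in the authors' values (123 against 10). Saturated probes were not left out of the background-corrected values at the 2-fold limit, where 34 higher probes on each array had both channels saturated. With neither background correction nor saturated probes, 149 probes were at least 2-fold higher with high salt. Of these, 41 were at least 1.5-fold lower with benidipine and 1 at least 1.5-fold higher. Of the 27 at least 2-fold lower there, 20 were at least 1.5-fold higher and 0 at least 1.5-fold lower. At the 3-fold limit in the background-corrected values, noise of each array alone is argued against. There 10000 reshufflings of the second array's ratios among probes of like intensity gave at most 18 opposite probes (6.72 on average) against 38 observed. Same-direction probes numbered 10 there, against 7.40 on average. At the lower limits reshuffling cannot decide, since both directions exceeded it, as they would if some probes were noisy on both arrays. At 2-fold, opposite probes were 121 against at most 83 (57.9 on average), and same-direction probes 142 against at most 92. At 1.5-fold they were 340 against at most 296 and 358 against at most 309. A vehicle sample that stood apart from its group and an effect of benidipine against that of high salt cannot be told apart, because the only vehicle RNA enters both ratios. The median of benidipine over normal over the 38 probes, signed by the first array, was 0.83 on the log2 scale, with 11 of them within 1.5-fold of normal diet, but selecting on both ratios moves this value too.

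With background correction, 358 probes were at least 1.5-fold changed the same way on both arrays, against 255 on average and at most 309 in 10000 reshufflings. These probes had within-array medians of 0.90 and 0.87 on the log2 scale, signed by direction. Their same-dye medians were 0.106 (bootstrap 95% interval 0.045 to 0.11) and -0.093 (-0.11 to -0.022). The intervals resampled probes, which are not independent replicates, so they give no precision across animals. Values that do not mix dyes thus held little of the change. Dye bias or noise of single spots is a candidate explanation, but these medians cannot decide it. Each same-dye value reuses readings from the ratios, the vehicle readings included. Selecting probes on both ratios therefore lowers these medians whatever the cause. These medians include 67 probes saturated in Cy5 on at least 1 array, whose Cy5 differences the ceiling limits. The medians were not computed without those probes, so saturation may account for part of the low values. Saturation of Cy5 is also a candidate explanation for part of the 358 probes. Without Cy5-saturated probes 291 were left, against 247 on average and at most 303 in reshufflings. Those reshufflings moved ratios among all probes before the saturated ones were left out. Ratios of saturated probes could thus enter them, so this comparison cannot decide how much saturation accounts for. A real change in the same direction under both high salt and benidipine was not tested separately and stays open for single probes.

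The balance of opposite and same-direction probes changed with the processing. The background-corrected values gave 340 opposite and 358 same-direction probes. Leaving out saturated probes alone gave 337 and 291, leaving out background correction alone gave 128 and 80, and both together gave 125 and 10. Median centring gave 233 and 2494, and same-dye values between arrays gave 257 and 1916.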
